A study of Pimephales promelas with 30 samples.

How the data were processed

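Total RNA from minnow brains was labelled and hybridised to a 2-colour cDNA array in a balanced interwoven loop. Per the labels' protocols, 600 ng of total RNA per labelling was used, and only RNA with an RNA integrity number of at least 6 and a 28S to 18S ratio of at least 1.4 was taken. The dyes were Cy3 and A647. Per the file headers, arrays were scanned on a GenePix 4200A at 635 nm (A647) and 532 nm (Cy3) and read with GenePix Pro 6. The 30 arrays lay on 15 slides, 2 per slide, and a slide held arrays of different treatments.

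The deposited scanner files give intensity per spot, as the mean pixel brightness of each channel and the median of the local background, neither subtracted nor normalized. The deposited signal-to-noise score of each channel was computed by the scanner software from spot and background pixels and is given as it came, per the file headers. The deposited percent values were computed by the same software, per the file headers, as the percent of a spot's pixels above background by 2 SD and the percent saturated. Every spot flag was 0 or above, so no spot was left out for a flag. The deposited series matrix holds log2 values; set against the scanner files, they are the log2 ratio of Cy3 over A647 after the scanner software's own Lowess, the opposite sign of the ratio used here. They correlated with the log ratios computed here, sign turned, at 0.867 to 0.987 per array. Column medians ran from −0.11 to 0.35. One column, for the array of 2.5 mg/L fish 1 and 5 mg/L fish 2, was stretched, with an SD of 4.00 against 0.53 to 1.67 in the other columns. The table was used only as an alternative, once as deposited and once with that column divided by log2 of 10.

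Background was corrected with normexp (offset 50) and log2 ratios of A647 over Cy3 were normalized by loess within each array in limma 3.58.1 (R 4.3.3), with water and Arabidopsis spots at weight 0. Arrays were not scaled to each other. A reading counted as above background when its signal-to-noise ratio was over 2, a definition chosen after the files were seen, and probes above background in at least 30 of 60 readings were tested. The 36 water and 6 Arabidopsis spots were not tested. Each spot was a probe of its own.

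Every probe's 30 log ratios were fitted on 15 fish values, summing to 0, and a dye term. Turning the direction of any 1 of the 30 arrays raised the median technical SD, from 0.24 to between 0.25 and 0.41. The 15 fish values were the replicates in limma's moderated tests, with all 5 groups sharing the spread and Benjamini-Hochberg adjustment over the 1003 probes. Results were 4 comparisons of a dose with control, the mean of the doses against control, the neighbouring doses, the linear trend with dose and an F test of any difference. Fish were separate animals, but those of a treatment came from 1 aquarium as the labels describe it, so p-values measure the spread between fish within aquaria. Each slide held 2 arrays, too few to fit a comparison within a slide; slide was tried as a block.

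Named genes followed a rule fixed before the data were examined. Only probes with a gene name counted, with 1 probe per gene, that of the highest mean intensity; values of the other tested spots of FABP10, cytochrome c oxidase subunit II and the 14 kDa apolipoprotein were added after the data were seen. For each dose against control, the mean of the doses and the trend, it takes up to 10 passing genes per direction at 10 mg/L and up to 5 elsewhere, if all 3 dosed fish lie on the same side of the control mean. Where none passes, the 5 smallest unadjusted p in each direction are given as values that did not pass, and for the F test the 5 smallest p. Where fewer than 5 genes lay on a side, all were given. For gene lists with 5 or more measured genes the rule names 2 members with the smallest p for 10 mg/L and 2 for the mean of the doses; no list reached that size. The 28 lists were fixed at the same time and tested with camera at a preset correlation of 0.01. Clone names were not linked to genes here, and the clones were reported as counts.

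The fit was tested on simulated data with 200 of 1003 probes changed at 10 mg/L against control, using each probe's own spread and independent probes. At 2-fold 49.3% of changed probes were recovered, at 4-fold 92.5% and at 8-fold 97.0%, and 6 of 803 unchanged probes were called. Probes of the real fish moved together, so these rates may not carry over to the real data. Sets of clones with like profiles, an analysis added after the data were seen, were formed by average linkage at a correlation of 0.85, and their means were tested by permutation F tests with 100000 resamples. Overlap between comparisons was set beside 1000 simulated draws of groups without effect. Alternatives covered the background correction, normalization, scaling, the filter, the unit of replication, slide and fish number as blocks, thresholds and leaving out each fish.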

Results

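RNA was measured in whole brain tissue of sub-adult fathead minnows (Pimephales promelas) that had been held for 10 days in water with RDX, a nitramine explosive that acts on the nervous system. The arrays covered 5 treatments: an acetone control (1% acetone) and 4 concentrations of RDX, 0.625 and 2.5 mg/L at the low end, 5 mg/L, and 10 mg/L as the highest. A dose of 1.25 mg/L was part of the exposure but was not on the arrays. Each treatment held 8 fish (48 fish in all), of which 3 per treatment were hybridised, giving 15 fish. Every fish was on 4 of the 30 arrays, 2 with each dye, in a loop that set each treatment directly against 2 others. Per the labels, the fish of a treatment were reared in a 25 L aquarium, so aquarium and dose cannot be told apart in any comparison.

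Each array carried 4224 spots, of which 4128 were cDNA clones known here only by plate and well. The files do not pair the clones with genes. A further 54 spots carried named cDNAs or cDNA pools, which stand for 36 named genes. These were counted by name, and apolipoprotein A-I appears under more than 1 name. Spots above background (signal-to-noise ratio over 2) made up 13.1% to 41.8% of a channel on an array. By treatment their share was 25.4% ± 4.04 (SD, n = 3) in controls, 26.1% ± 1.07 at 0.625 mg/L, 26.7% ± 0.89 at 2.5 mg/L, 23.1% ± 8.98 at 5 mg/L and 29.5% ± 4.94 at 10 mg/L. The lowest shares belonged to 5 mg/L fish 5 (17.5%) and 5 mg/L fish 2 (18.3%). Above background in at least 30 of the 60 channel readings were 1003 probes: 983 clones, 19 spots of 13 named genes and 1 spot of a liver cDNA pool. The median SE of a difference from control was 0.29 on the log2 scale.

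The median SD between fish of one treatment was 0.36 on the log2 scale, and the technical SE of a fish value, from its repeat arrays, was 0.12. The spread was unequal: the median SD between the 3 fish was 0.58 at 5 mg/L, and 0.28, 0.21, 0.23 and 0.24 in the control, 0.625, 2.5 and 10 mg/L groups. The tests used 1 spread for all groups. SEs and p-values therefore tended to be too large in comparisons without the 5 mg/L group and too small in those with it. A first principal component took 49.5% of the variance among fish, and its highest scores were those of 5 mg/L fish 2 and control fish 2. A second took 20.6% and set 5 mg/L fish 5 apart from all other fish. Between the highest and the lowest fish, 80 of the 1003 probes differed by more than 4 on the log2 scale.

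**Figure D1:**
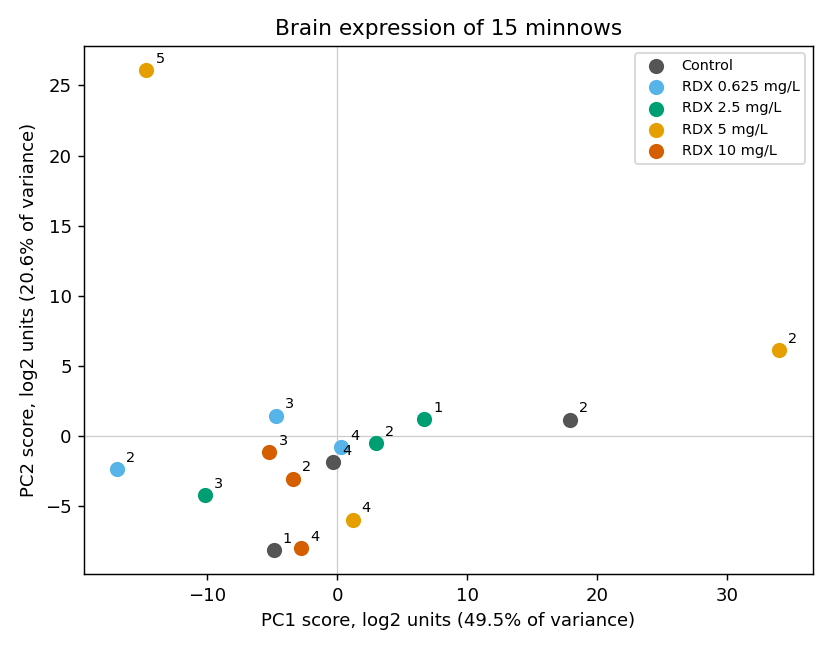
Scores of the 15 fish on the first principal component (x axis, 49.5% of the variance) and the second (y axis, 20.6%) of log2 levels over 1003 probes; each point is a fish, coloured by treatment and marked with its fish number. The 5 mg/L fish 2 and 5 lie far from each other and from the other fish, and control fish 2 lies on the side of 5 mg/L fish 2.

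Sets of clones moved together across the fish. Grouped by the correlation of their fish profiles, the 3 most numerous sets held 88, 47 and 31 clones, spread over all 16 blocks of the array. The set of 88 clones was low in a single fish, 5 mg/L fish 5, at −2.10 on the log2 scale against the mean of all fish, while the other 14 fish lay between −0.31 and 0.72. The set of 47 clones ranged over 36.4-fold, from −1.80 in 0.625 mg/L fish 2 to 3.39 in 5 mg/L fish 2, with control fish 2 at 2.36. The set of 31 clones ranged over 11.9-fold, from −1.37 in control fish 4 to 2.21 in 5 mg/L fish 2. None of the 3 set means differed between treatments in a two-sided permutation F test over the 15 fish (p = 0.947, 0.471 and 0.302; adjusted p = 0.947, 0.706 and 0.706 over the 3 tests). These sets, and the correlation of 0.85 that formed them, were chosen after the data were seen; 15 sets held 10 or more clones and only 3 were tested.

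**Figure D2:**
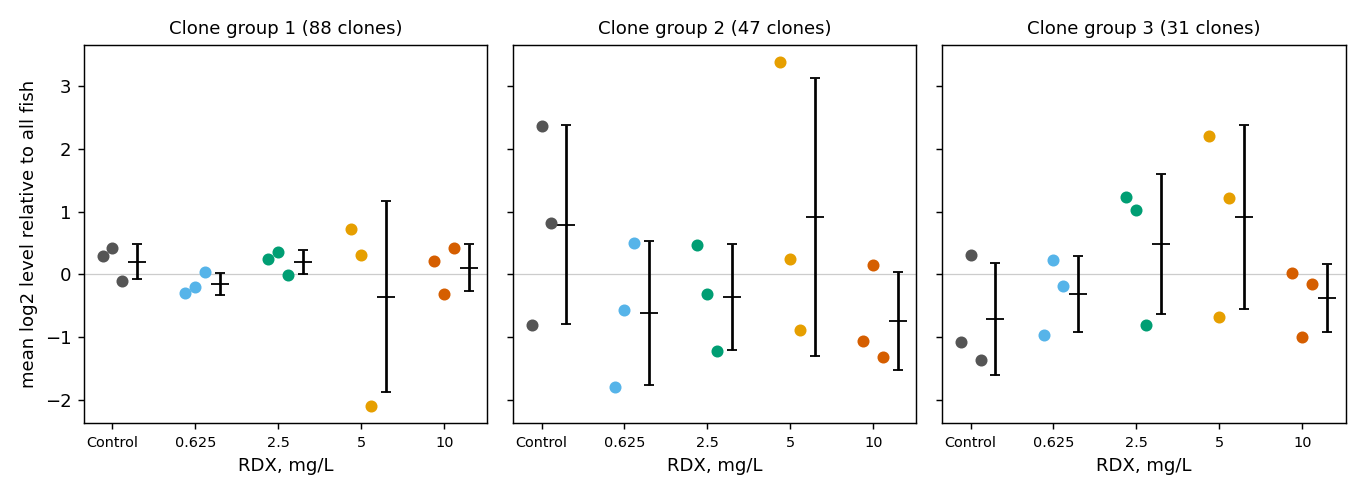
Mean log2 level, relative to the mean of all fish (y axis), of the 3 most numerous sets of clones with like profiles, by RDX dose in mg/L (x axis); each point is a fish, and the bar with whiskers beside it is the treatment mean ± SD of 3 fish. Clone group 1 is low in 5 mg/L fish 5 at −2.10, and clone group 2 reaches 3.39 in 5 mg/L fish 2 and 2.36 in control fish 2.

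Among the named genes, several spots stood high in 1 fish, 2.5 mg/L fish 2. FABP10, the basic fatty acid binding protein of liver, was at 3.22 in this fish on the spot in well M16 (log2, against the mean of all fish), where the other 14 fish reached at most 1.21. Apolipoprotein A-I, a protein of plasma lipoproteins, was at 1.88 (other fish at most 0.54) and parvalbumin, a calcium buffer of fast muscle and some neurons, at 1.80 (at most 1.05). The 14 kDa apolipoprotein was at 2.13 and 1.07 on the spots in wells M15 and M19, and cytochrome c oxidase subunit II, a mitochondrial transcript, at 1.24 in well N21. Among spots too dim to be tested, FABP10 was at 3.58 in well M14 (16 readings above background), apolipoprotein C-I at 1.16 (3 readings), a second apolipoprotein A-I at 1.15 (13 readings) and ribosomal protein L10a, not a liver marker, at 1.04 (15 readings). Other dim spots were lower: another apolipoprotein A-I at 0.34 (14 readings), the 14 kDa apolipoprotein at 0.60 (M17) and 0.26 (M13), and transferrin, a liver marker, at 0.02 (6 readings). All 4 arrays of this fish gave values above 0 on the spots of FABP10 (M16), both apolipoproteins and parvalbumin named here. For FABP10 they ran from 2.80 to 3.64 in well M16, and from 3.23 to 3.93 in well M14. The ranges were wider for apolipoprotein A-I in well M6 (0.66 to 2.775) and parvalbumin in well M20 (1.18 to 2.81). Spots of one gene disagreed: the FABP10 spots in wells M18 and M12 were at 0.37 and 0.40 in the same fish, the third tested spot of the 14 kDa apolipoprotein was at 0.18, and cytochrome c oxidase subunit II was at 0.03 and 0.20 in wells N17 and N15. This fish and these spots were singled out after their values were seen, and 3 water spots of the same plate also gave signal. Gene names are those the array layout gives to each well, and whether that layout holds for this plate was not tested.

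**Figure D3:**
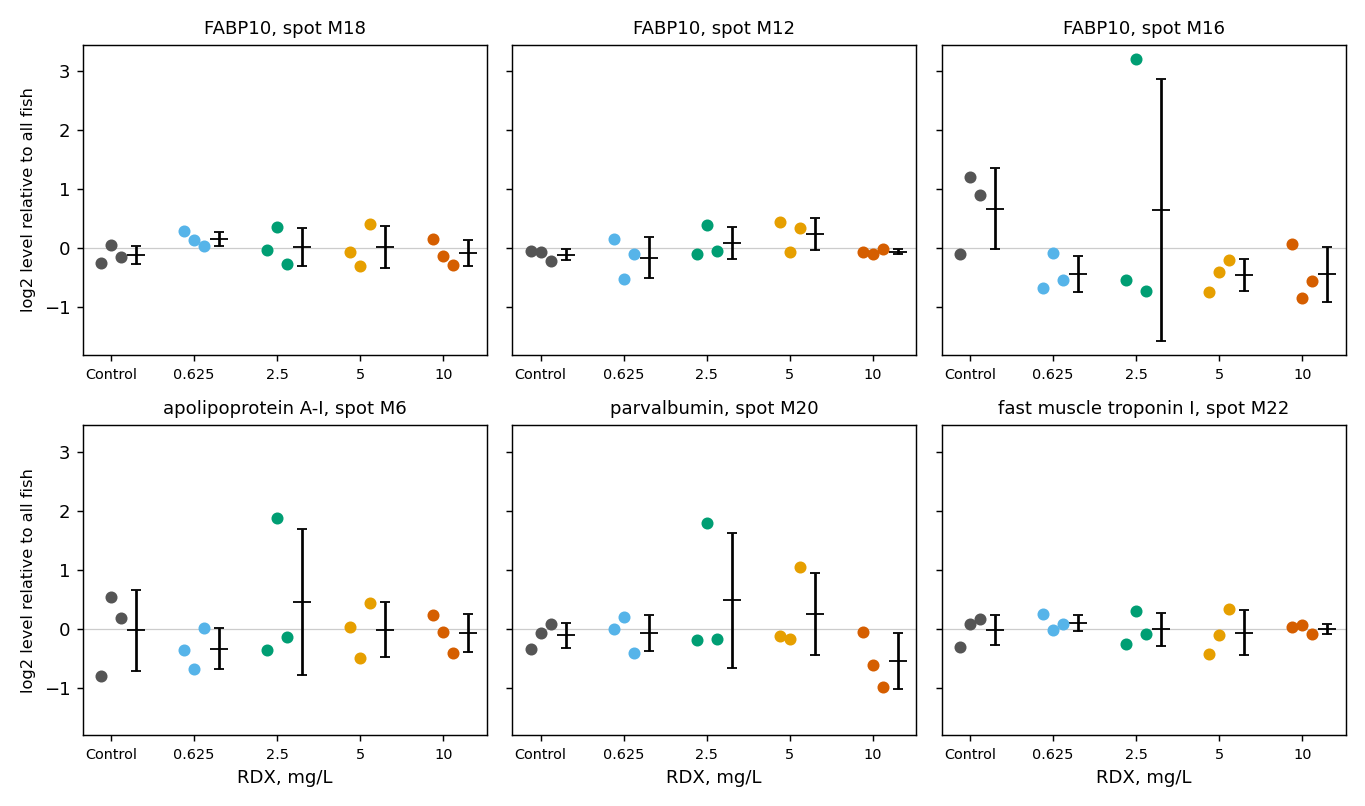
Log2 level relative to the mean of all fish (y axis) of 6 spots of named cDNAs by RDX dose in mg/L (x axis); each point is a fish, and the bar with whiskers is the treatment mean ± SD of 3 fish. The highest point at 2.5 mg/L is fish 2, at 3.22 for FABP10 in well M16 but 0.37 for FABP10 in well M18.

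At 10 mg/L, the highest dose, no probe passed an adjusted p of 0.05 in limma's moderated test against control. Of the 1003 probes, 2 had an unadjusted p under 0.05, where 50.2 would be expected by chance with independent probes. Both were clones and both were higher. The spread shared with the more variable 5 mg/L group also tended to raise the p-values of this comparison. Of the named genes, those on the lower side with the smallest p were parvalbumin at −0.44 ± 0.49 (log2 difference ± SE), the 14 kDa apolipoprotein at −0.21 ± 0.31, the mitochondrial cytochrome c oxidase subunit II at −0.15 ± 0.26, malate quinone oxidoreductase at −0.13 ± 0.22 and keratin 5b at −0.10 ± 0.24. FABP10, fast muscle troponin I, myosin heavy chain and a prolactin-like protein lay between 0.00 and 0.03. None of these 9 values exceeded its SE, and the smallest unadjusted p among them was 0.390. Each is from the brightest spot of its gene, well M18 for FABP10. Other tested spots were at 0.05 ± 0.21 (M12) and −1.11 ± 0.79 (M16) for FABP10, −0.71 ± 0.51 (M15) and −0.10 ± 0.20 (M23) for the 14 kDa apolipoprotein, and 0.01 ± 0.24 (N15) and −0.10 ± 0.35 (N21) for cytochrome c oxidase subunit II. The central 90% of all probes lay between −0.60 and 0.41, and 43 probes differed by more than 1 on the log2 scale without passing. With arrays as replicates and with generalized least squares the count was also 0.

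At 5 mg/L, again no probe passed, and 39 had an unadjusted p under 0.05, 18 higher and 21 lower. Parvalbumin was at 0.36 ± 0.49, FABP10 at 0.13 ± 0.22, keratin 5b at 0.08 ± 0.24, malate quinone oxidoreductase at 0.05 ± 0.22 and cytochrome c oxidase subunit II at 0.04 ± 0.26. Other spots of these genes went both ways: FABP10 at 0.35 ± 0.21 (M12) and −1.12 ± 0.79 (M16), and cytochrome c oxidase subunit II at 0.07 ± 0.24 (N15) and −0.31 ± 0.35 (N21). Those of the 14 kDa apolipoprotein were at −0.57 ± 0.51 (M15) and 0.01 ± 0.20 (M23). Myosin heavy chain, a motor protein of muscle, was at −0.30 ± 0.20 and laminin receptor 1 (ribosomal protein SA) at −0.19 ± 0.30. The chaperonin subunit cct3, which helps fold actin and tubulin, was at −0.16 ± 0.35, the 14 kDa apolipoprotein at −0.11 ± 0.31 and an S100-like calcium binding protein at −0.06 ± 0.23. The smallest adjusted p over all probes was 0.686. The count depended on 1 fish: without 5 mg/L fish 4, 14 clones passed (1 higher, 13 lower). The 2 fish then left, 2 and 5, had the lowest shares of spots above background (18.3% and 17.5%) and lay farthest from the mean profile (1.12 and 0.95, root mean square log2). With arrays as replicates 5 probes passed, and with generalized least squares 2.

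At 2.5 mg/L, the highest named values were parvalbumin at 0.59 ± 0.49 and apolipoprotein A-I at 0.48 ± 0.52, and in each only 1 of the 3 exposed fish lay above the control mean. FABP10 (0.13 ± 0.22), the S100-like protein (0.13 ± 0.23) and keratin 5b (0.10 ± 0.24) followed. On the lower side were cct3 at −0.23 ± 0.35, cytochrome c oxidase subunit II at −0.22 ± 0.26, the prolactin-like protein at −0.18 ± 0.20, malate quinone oxidoreductase at −0.03 ± 0.22 and myosin heavy chain at −0.03 ± 0.20. Other spots gave 0.20 ± 0.21 (M12) and −0.02 ± 0.79 (M16) for FABP10, and −0.15 ± 0.24 (N15) and 0.40 ± 0.35 (N21) for cytochrome c oxidase subunit II. No probe passed in limma's test, and 6 had an unadjusted p under 0.05 (2 higher, 4 lower). Arrays as replicates and generalized least squares also gave 0.

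At 0.625 mg/L, laminin receptor 1 was at 0.33 ± 0.30, FABP10 at 0.27 ± 0.22, myosin heavy chain at 0.27 ± 0.20, the S100-like protein at 0.21 ± 0.23 and keratin 5b at 0.18 ± 0.24. Lower values were those of cytochrome c oxidase subunit II (−0.32 ± 0.26), apolipoprotein A-I (−0.31 ± 0.52), the prolactin-like protein (−0.28 ± 0.20), cct3 (−0.27 ± 0.35) and the 14 kDa apolipoprotein (−0.04 ± 0.31). Other spots differed: FABP10 was at −0.05 ± 0.21 (M12) and −1.10 ± 0.79 (M16), cytochrome c oxidase subunit II at 0.13 ± 0.24 (N15) and −0.02 ± 0.35 (N21), and the 14 kDa apolipoprotein at −0.41 ± 0.51 (M15) and 0.16 ± 0.20 (M23). The smallest unadjusted p among these was 0.179, and none passed. Over all probes limma's test gave 0 calls, with 5 at an unadjusted p under 0.05 (3 higher, 2 lower), and arrays as replicates and generalized least squares gave 0.

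In the mean of the 4 doses, 12 exposed fish against 3 controls, FABP10 was at 0.14 ± 0.18 and above the control mean in 8 of 12 exposed fish, and parvalbumin was at 0.14 ± 0.39. The S100-like protein was at 0.07 ± 0.18, keratin 5b at 0.07 ± 0.19 and fast muscle troponin I at 0.03 ± 0.18. Cytochrome c oxidase subunit II was at −0.16 ± 0.20 and below the control mean in 9 of 12 exposed fish, cct3 was at −0.18 ± 0.27 and the prolactin-like protein at −0.11 ± 0.15. The 14 kDa apolipoprotein (−0.06 ± 0.24) and malate quinone oxidoreductase (−0.02 ± 0.17) were the last named by the rule. On other spots FABP10 was at 0.14 ± 0.17 (M12) and −0.84 ± 0.62 (M16), and cytochrome c oxidase subunit II at 0.01 ± 0.19 (N15) and −0.01 ± 0.27 (N21). Those of the 14 kDa apolipoprotein were at −0.38 ± 0.40 (M15) and 0.04 ± 0.16 (M23). No probe passed in limma's test, with 5 at an unadjusted p under 0.05, and no probe passed with arrays as replicates or generalized least squares.

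Across the dose series, the test for any difference among the 5 groups called no probe, and 10 had an unadjusted p under 0.05. Its smallest named p were those of myosin heavy chain (0.173), parvalbumin (0.334), laminin receptor 1 (0.489), the prolactin-like protein (0.496) and cytochrome c oxidase subunit II (0.617), all from limma's F test. With arrays as replicates, 47 probes passed it, and with generalized least squares 0. The linear trend with dose called none, with 11 at an unadjusted p under 0.05, and 0 by either other fit. Slopes per mg/L were 0.02 ± 0.02 for the prolactin-like protein and 0.01 ± 0.03 for cct3, and 0.00 for cytochrome c oxidase subunit II and apolipoprotein A-I. They were −0.05 ± 0.04 for parvalbumin, −0.03 ± 0.03 for laminin receptor 1, −0.02 ± 0.02 for the 14 kDa apolipoprotein, −0.02 ± 0.02 for keratin 5b and −0.02 ± 0.02 for myosin heavy chain.

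Between neighbouring doses, limma's test called no probe from 0.625 to 2.5 mg/L, from 2.5 to 5 mg/L or from 5 to 10 mg/L, and 1, 15 and 54 probes had an unadjusted p under 0.05. Without 5 mg/L fish 4, 12 clones passed from 2.5 to 5 mg/L (all lower at 5 mg/L) and 19 from 5 to 10 mg/L (17 higher and 2 lower at 10 mg/L). With arrays as replicates, 5 and 79 probes passed in these comparisons, and with generalized least squares 0 and 0. The step from 0.625 to 2.5 mg/L had 0 calls by both other fits.

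No call was shared between doses, since limma's test made none. Across probes, which are not independent replicates, the log2 differences from control at 10 and 2.5 mg/L correlated at r = 0.79, those at 10 and 0.625 mg/L at 0.75 and those at 2.5 and 0.625 mg/L at 0.74. Those at 5 mg/L correlated less with the others, at 0.15, 0.48 and 0.21 with 10, 2.5 and 0.625 mg/L. With scaling between arrays these 3 correlations were 0.38, 0.65 and 0.42, and with the series matrix as deposited 0.12, 0.11 and −0.10. The last also depended on single fish: the correlation of RDX 5 mg/L minus control and RDX 0.625 mg/L minus control was 0.75 without 5 mg/L fish 2 and −0.39 without 5 mg/L fish 5. The 3 control fish are common to these comparisons. Simulated groups without any effect, against common controls, gave median correlations from 0.54 to 0.57, with 95% of the 1000 draws between −0.44 and 0.95 for the pair of 10 and 2.5 mg/L. The covariance of that pair was 0.128, against a simulated mean of 0.107 and a 95% range from −0.07 to 0.48. All 6 correlations and covariances lay within their simulated ranges. For the correlations, the lower bounds lay between −0.55 and −0.44 and the upper bounds between 0.94 and 0.95. Ranges this wide could exclude little. They were much the same for pairs with 5 mg/L, although the fish of that group varied more (median SD 0.58). The draws therefore cannot be used to judge the lower correlations of 5 mg/L. The 3 controls were too few to be split between comparisons.

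The gene lists fixed for brain tissue could hardly be addressed with these names. None of the 28 lists had 5 measured genes: skeletal muscle markers had 3 (fast muscle troponin I, myosin heavy chain and parvalbumin), and 9 other lists had 1 each. Lists for neurons, myelin, astrocytes, GABA and glutamate signalling and ion channels had no named gene on the array. Without the filter on dim probes, the list of liver and egg yolk markers reached 6 entries, each counted as a gene. Of these, 3 are named as apolipoprotein A-I. Counted as 1 gene, they leave the list short of the 5 genes required. FABP10 was not in this list. Between 0.625 and 2.5 mg/L, 1 of the 8 comparisons tried, the list's camera p was 0.00893 (median log2 difference 0.27). It was 0.0948 with an estimated correlation and 0.227 by fry. Without 2.5 mg/L fish 2, a check chosen after the values were seen, the camera p was 0.652. In the 4 comparisons with control, the list's camera p lay between 0.132 and 0.971.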

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

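The tests of the preceding spot, of the named spots, of low signal and of RDX dose were chosen after the results were seen, and so were the sets of clones; those of array position, single arrays and slide flaws were set before. Of the 36 water spots, which should carry no cDNA, 3 gave signal above background in 47, 36 and 58 of the 60 readings, in wells P21, O18 and O20 of the plate that holds the named cDNAs. Signal in wells listed as water leaves open that gene names on this plate are misassigned, which was not tested and would bear on every named value. Groups of 3 fish are too small for the test of single samples far from the others.

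The median of the other water spots was 0 readings above background and the highest 12. Carry-over from the spot printed before by the same pin stays open: in 0 of the 3 cases was the preceding spot brighter, but all 3 preceding wells hold water and were bound to be dimmer than spots picked for their signal. A local effect of the array position stays open. The 53 clones compared had a median correlation of −0.26 with the mean fish profile of the water spots. They were picked by row and column within blocks, not by the blocks of these 3 spots, so they need not lie beside them. A target shared with the named spots stays open and is a candidate explanation: the 20 named and pool spots had a median correlation of 0.62 with the water profile, above the upper bound of 10000 random draws of 20 clones (0.37), and the S100-like protein and fast muscle troponin I reached 0.95 and 0.92. Of the spots used in the comparisons, keratin 5b was at 0.81 and FABP10 (M18) at 0.78, but cytochrome c oxidase subunit II (N17) at −0.03. The FABP10 spots in wells M16 and M12 were at 0.41 and 0.09. Values of spots close to the water profile may therefore not be particular to the named gene, which was not tested. No biological explanation was tested.

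The sets of clones that vary several fold between fish were weighed as the second pattern. Error of single arrays is argued against: the residual SD between arrays was at most 0.0964 of the SD between fish in the 3 sets. A local flaw of the slides is argued against too, since each set lay in all 16 blocks. A low signal of a fish's labelled RNA is a candidate explanation that stays open: over the 15 fish, the share of spots above background fell with the distance from the mean profile (Spearman's rho = −0.588, permutation p = 0.024; Pearson's r = −0.756, permutation p = 0.00111). Without 5 mg/L fish 5 and 10 mg/L fish 4, farthest from the median share, r was −0.765. That check kept 5 mg/L fish 2, the fish farthest from the mean profile (1.12, root mean square log2), whose share was 18.3%. It therefore cannot say whether the relation holds without both 5 mg/L fish 2 and 5. A fish whose abundant clones fell would also lose spots above background. RDX dose cannot be told apart from fish-to-fish variation with 3 fish per group, with a smallest adjusted permutation p of 0.706 over the 3 sets.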

How the results depend on the processing

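The rescaled matrix, the pixel rule for background, the ratios without signal, the permutation tests of clone sets, the fit without the 2 fish of lowest signal and the fit without the 5 mg/L group were chosen after the data were seen. Of 372 counts of changed probes under alternatives, 357 equalled the count of 0 reported. With arrays as replicates, 5 probes passed for 5 mg/L against control, 5 from 2.5 to 5 mg/L, 79 from 5 to 10 mg/L and 47 in the F test; this fit counts the 4 arrays of a fish as separate. Generalized least squares gave 2 at 5 mg/L against control; the cause was not tested. Without the 2 fish of lowest signal every count was 0, but both are 5 mg/L fish, so its comparisons then rest on 1 fish assumed to vary like those of other groups. The 4 counts fitted without the 5 mg/L group were 0. An unadjusted p under 0.05 with 1.5-fold, a looser threshold, gave 2, 33, 4 and 3 probes at 10, 5, 2.5 and 0.625 mg/L against control, 4 for the mean of the doses, 8 from 2.5 to 5 mg/L and 40 from 5 to 10 mg/L. Leaving out single fish gave 0 to 14 calls at 5 mg/L against control, 0 to 12 from 2.5 to 5 mg/L and 0 to 19 from 5 to 10 mg/L, the highest without 5 mg/L fish 4, and 0 elsewhere; the cause was not tested. Without the filter on dim probes, where more genes could be tested, 1 gene list result had a camera p under 0.05 (0.00893). It was adjusted over that 1 list alone, not over the comparisons tried. The list has fewer than 5 genes when apolipoprotein A-I is counted once, so it does not meet the rule. With an estimated correlation (0.0948) or by fry (0.227) its p was not under 0.05. The estimated correlation, fry and all probes of a list could give no value with the filter, as no list had 5 genes. Flagged spots kept moved nothing, since no spot was flagged.

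Fish number as a replicate block left every count at 0. Over 20 pairs of fish with one number, correlations of their deviations from the group mean ran from −0.74 to 0.80, and 8 were above 0.1. Fish of different numbers were not set beside them, so whether the numbers pair the fish cannot be told from these values. Slide as a block also gave 0 throughout. Scaling between arrays moved the correlations of 5 mg/L with 10, 2.5 and 0.625 mg/L from 0.15, 0.48 and 0.21 to 0.38, 0.65 and 0.42, and the series matrix as deposited that with 2.5 mg/L to 0.11. The correlation of 5 with 0.625 mg/L turned from 0.21 to −0.21 with the replicate block and to −0.39 without 5 mg/L fish 5, was −0.10 with the series matrix as deposited (0.22 with its stretched column rescaled), and was 0.75 without 5 mg/L fish 2. Of 1827 named values, 1771 moved by less than 1 SD between fish, but 172 had the opposite sign, so the printed directions are not settled. With separate channels cct3 went from −0.27 to 0.24 at 0.625 mg/L and from −0.23 to 0.20 at 2.5 mg/L, and the S100-like protein from −0.06 to 0.30 at 5 mg/L; the cause was not tested. Signal over background limited the comparison to 1003 of 4224 spots.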

Other observations

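The test of how alike the clones of a set are, the comparison of clone plates and the 2 genes named here were chosen after the results were seen; the test of other splits was set before. Hemoglobin alpha, the oxygen carrier of red cells, was above background in only 24 of 60 readings on its brightest spot and so was not tested. There it was at 2.40 in control fish 2, against at most 0.74 in the other fish. Its dimmer spots, in wells N5 and N1, were at 0.67 and −0.03 in control fish 2, with 2 and 0 readings above background. Superoxide dismutase 3, an extracellular antioxidant enzyme, was above background in 18 readings and was at 1.81 in the same fish and 1.19 in 5 mg/L fish 2. Control fish 2 and 5 mg/L fish 2 correlated at r = 0.80 across probes, and 0.625 mg/L fish 2 ran opposite to both (r = −0.83 and −0.85); these were picked from all pairs of fish.

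The near-identical profiles of clones within a set may come from spots that carry the same transcript. In 1 of the 3 sets the median clone lay within 1.5 times the technical SE of a fish value. The ratios in the sets of 88, 47 and 31 clones were 1.52, 1.75 and 1.39. The sets were formed by the likeness of these same profiles, so closeness to the set's profile was partly imposed. These ratios therefore cannot decide the question, which stays open.

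Other splits of the fish gave as many probes at an unadjusted p under 0.05 in most cases. For the mean of the doses, 85 of 100 splits did so (real count 5, highest other 320). For the linear trend it was 74 of 100 (11, highest other 356), and for the F test 73 of 100 (10, highest other 195), so chance cannot be excluded for these. The highest of these counts are many times the real ones, but each is a maximum over many splits, and the probes moved together. Whether they reflect a structure among the fish was not tested. With 3 fish against 3 there are 10 splits, too few for a share under 0.05, and bracketed counts of splits include the real one. There the real counts and the highest others were 2 and 49 at 10 mg/L (9 splits as large), 39 and 316 at 5 mg/L (7), 6 and 97 at 2.5 mg/L (7) and 5 and 44 at 0.625 mg/L (7). Between neighbours they were 1 and 79 from 0.625 to 2.5 mg/L (10), 15 and 211 from 2.5 to 5 mg/L (10) and 54 and 307 from 5 to 10 mg/L (8).

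Clones from the F and R plates, whose meaning the files do not give, were compared as sets in 16 tests. At 10 mg/L the camera p of the 576 F clones was 0.0294 (median log2 difference 0.03). Camera p under 0.05 also came for F and R clones at 0.625 mg/L (0.0255 and 0.0281) and for F clones from 5 to 10 mg/L (0.0261). At 0.625 mg/L the F clones were higher and the R clones lower, each relative to the other probes. F and R clones make up 983 of the 1003 probes, so the 2 tests of a comparison nearly mirror each other and are not separate results. With an estimated correlation none of the 16 was under 0.05, the lowest being 0.171.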
